A study of Danio rerio with 16 samples.

How the data were processed

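Liver RNA of zebrafish was measured on 16 arrays in 4 groups of 4: normally fed fish given PBS, normally fed fish given LPS, overfed fish given PBS and overfed fish given LPS. Per the labels, each array held a pool of livers of 3 fish taken 3 hours after injection of 10 µg of LPS or of PBS, after 8 months of either diet. Replicates are separate pools per the labels.

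Total RNA was labelled with Cy3 and hybridized with spike-in controls to Agilent 1-colour arrays of design 026437, per the labels and the file headers. The spot intensity in each array file is the processed signal of Feature Extraction, which per the file headers subtracts background and detrends within the array, with no scaling between arrays. The median pixel intensity of the spot and of its local background are also as deposited by the authors. Flags for spots well above background, saturated or non-uniform were deposited by the authors in the same files. The version of Feature Extraction is 10.7.3.1 per the file headers and 10.4.0.0 per the submitters' processing notes, and this difference could not be settled. The authors also deposited a gene table of log2 values, made per the deposited text with GeneSpring GX 12.6: probes with flags in 2 of 4 conditions were kept, arrays were shifted to the 75th percentile, values between percentiles 20 and 95 were kept, probes were reannotated, and each gene was centred on its median. That table has 14188 entries, of which 10918 have an Entrez gene, and it was used as an alternative. The authors' quantitative PCR of 6 genes was not analysed here.

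Each array held 43803 non-control spots of 43603 different probes, and 1417 control spots, which were left out. Spots with non-uniformity or population outlier flags were set to missing, which left 1.18% of the tested values missing. No spot was saturated. The level was log2 of the processed signal minus the array's 75th percentile of it, and spots of one probe were averaged. A probe was tested where it was well above background on at least 3 of the 4 arrays of a group, which held for 22749 probes. The probe with the highest mean represented each gene, and probes without a gene were kept as features, for 15021 features in all.

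Gene names came from the accession of the probe through the reference gene table and from the authors' deposited table. Of 26981 probes with a RefSeq accession, 25069 matched, and 16689 probes were paired with a gene in the authors' table. Of 12646 probes with both, 12031 had the same gene and 615 differed. In all 29112 probes had a gene, for 15933 genes, 14491 had none, and for 719 the symbol of the deposited table was kept. The probe annotation in the file headers is on an older genome build than the reference, so no coordinates are given.

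All 16 arrays entered a linear model of group means in limma 3.58.1 with R 4.3.3 and data.table (version 1.17.8), with a shared estimate of the spread. The comparisons were LPS against PBS in each diet, overfed against normally fed after each injection, and the difference of the LPS effects. P-values were moderated with eBayes and adjusted with the Benjamini-Hochberg method over all features of a comparison, with a threshold of 0.05, and tests were two-sided. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the lowest signal well above background and the probe's own signal. A gene with any probe well above background on any array of a group counted as measured there. Some sizes given with an SE can therefore rest on group means near background.

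There were 41 gene lists of liver functions, immune pathways and markers of other cell types, and each list with at least 5 measured members was tested. Lists were compared with the other features by camera with a preset correlation of 0.01 and with an estimated correlation, and tested alone with fry. The grouping, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from alternatives described as chosen after the data were seen. By that rule the text names, for each comparison, the 10 largest rises and 10 largest falls with a gene symbol among features past the threshold whose groups did not overlap. For each list described it also names up to 4 measured members with the largest change among those past the threshold, or among all members where none passed, and other list members may be given with their values.

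Alternatives were normexp background correction of the median signal with an offset of 50, since the deposited files hold no mean signal, quantile normalization, centring on the median of detected probes, other filters and summaries of probes, the arrays of the compared groups alone, replicate number or slide as a block, array weights, a trended and robust prior, other thresholds, the authors' deposited table and leaving out each array. The normexp offset exceeded the median processed signal of the overfed arrays of slides 5 and 6 (18.8 to 31.4). It lay below that of the other arrays (99.4 to 545.4), so this setting may act unequally on the diets. Slides and scan days, taken from the file headers, were tested as batches. Correlations across arrays were tested by permutation. Depth was given as the brightness of the array and the share of spots well above background, which lay between 35.7% and 77.6%, and the number of arrays limits the precision.

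The tests were checked on simulated data with the real means and spread, in which 200 features were changed. Noise was drawn independently for each feature, so the simulated arrays held no correlation between genes and no differences between slides or in the tissue of the pools. For LPS in normally fed fish, over 15021 features, 4% of features changed by log2 1, 40% of those changed by 2, 78% of those changed by 3 and 92% of those changed by 4 were called, with 8 unchanged features. For LPS in overfed fish the shares were 0%, 46%, 66% and 76%, with 5 unchanged features. For diet after PBS they were 2%, 50%, 56% and 92%, with 12 unchanged features, and for diet after LPS 6%, 42%, 70% and 84%, with 3 unchanged features. None of 40 unchanged lists was called in any of these comparisons. These lists were random features with independent noise, so they do not check the preset correlation of camera on lists of correlated genes. For the same reason the numbers of unchanged features called do not carry over to the real arrays.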

Results

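Liver RNA of adult zebrafish was measured on 16 1-colour oligonucleotide arrays. The fish were kept for 8 months on a normal feeding schedule or were overfed with additional chow meals, and were then injected into the body cavity with phosphate-buffered saline (PBS) or with 10 µg of lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that triggers innate immune signalling. Each array held RNA from a pool of the livers of 3 fish collected 3 hours after injection, and each of the 4 combinations of diet and injection was represented by 4 pools. Levels are given as log2 of the processed signal relative to the 75th percentile of the same array, so a level of 0 equals that percentile. A total of 15021 features were tested, of which 11992 carried a gene symbol. The number of arrays limits the precision of every value given here.

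The share of spots well above background was 42.5% to 52.4% in normally fed fish given PBS, 39.4% to 55.7% in normally fed fish given LPS, 37.5% to 77.6% in overfed fish given PBS and 35.7% to 52.5% in overfed fish given LPS. The arrays came from 6 slides scanned on 3 days, and every slide and every scan day held arrays of a single diet. The 75th percentile of the processed signal lay between 694.1 and 4848.3 on the 8 arrays of normally fed fish and between 117.5 and 844.9 on the 8 arrays of overfed fish. Diet therefore could not be told apart from scan day in any comparison between diets.

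Transcripts typical of the ovary, which a liver pool can hold if gonadal tissue is collected with it, varied widely between pools. The mean of the 18 measured oocyte and gonad transcripts, relative to each gene's mean over all arrays, was 2.39 ± 1.48 (SD, n = 4) in normally fed fish given PBS, -0.27 ± 0.54 (SD, n = 4) in normally fed fish given LPS, -1.36 ± 3.12 (SD, n = 4) in overfed fish given PBS and -0.76 ± 3.28 (SD, n = 4) in overfed fish given LPS. The mean of the 34 hepatocyte identity genes was -0.4 ± 0.95 (SD, n = 4) in normally fed fish given PBS, -0.63 ± 1.69 (SD, n = 4) in normally fed fish given LPS, where replicate 2 stood at -3.14, 0.59 ± 0.49 (SD, n = 4) in overfed fish given PBS and 0.45 ± 0.48 (SD, n = 4) in overfed fish given LPS.

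**Figure D1:**
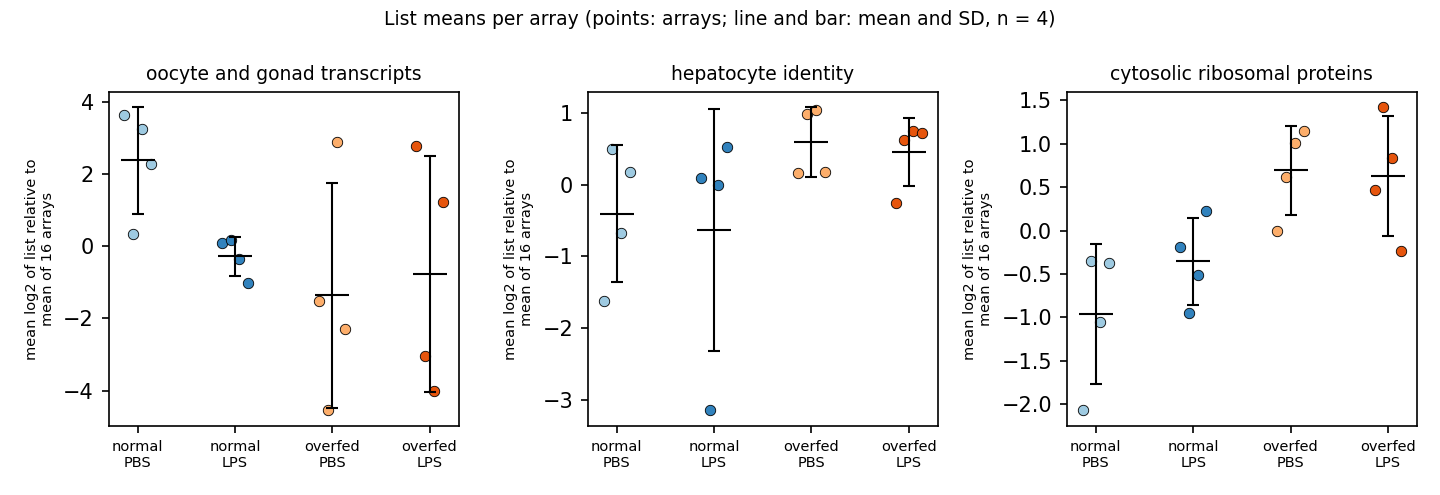
Mean log2 level of the oocyte and gonad list, the hepatocyte identity list and the cytosolic ribosomal protein list on each array, relative to each gene's mean over all 16 arrays. Points are arrays grouped by diet and injection, and bars give the group mean with the SD over 4 arrays. The oocyte mean spans -4.55 to 2.91 within overfed fish given PBS, and a single array of normally fed fish given LPS stands at -3.14 for the hepatocyte genes.

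To ask how the normally fed liver responds to an inflammatory stimulus, LPS was compared with PBS in normally fed fish, and immune signalling genes had the highest rises among named genes. The inflammatory cytokine il1b rose at least 20.9-fold (adjusted p = 0.00329), from a level of -3.93 ± 0.42 (SD, n = 4) after PBS, not well above background, to 1.60 ± 0.91 (SD, n = 4) after LPS. The chemokines cxcl18b and ccl20a.3 rose by 5.54 ± 0.51 (SE, n = 4 arrays per group) and 5.58 ± 0.83 on the log2 scale. The transcription factor batf2 rose at least 22.0-fold, from -4.65 ± 0.53 to 1.67 ± 0.34 (SD, n = 4), and the stress-induced transcription factor atf3 rose by 5.50 ± 0.71 (SE). In all, 131 of 15021 features passed the threshold in limma's test, 121 higher and 10 lower after LPS, and 2903 had an unadjusted p below 0.05. For each of the 131 the measured arrays of a group lay apart from those of the other. After normexp background correction the split was 332 higher and 427 lower.

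Other named genes that rose in normally fed fish were cd83, a surface marker of activated dendritic cells, by 6.10 ± 0.94 (SE), and mxf, an interferon-induced Mx GTPase, by 5.82 ± 0.77, the latter measured on 3 of the 4 LPS arrays. The membrane-fusion protein gene snap23.2, measured on 3 of the 4 PBS arrays, rose by 5.2 ± 0.97 and the metalloprotease gene adam10b by 4.95 ± 0.58. The NADPH oxidase organiser noxo1a rose at least 9.98-fold (adjusted p = 0.0383). The level of adam10b after PBS, -4.34 ± 0.8 (SD, n = 4), was as low as that of noxo1a, -4.33 ± 0.73, so its size is uncertain. Of the genes that were lower after LPS, diabloa, which encodes a mitochondrial protein that promotes apoptosis, fell by 4.37 ± 0.95 (SE), the chemokine ccl39.1 fell by 3.97 ± 0.75 and the transcriptional repressor her2 fell by 3.83 ± 0.75. The RNA-binding protein gene cpeb4a fell by 3.29 ± 0.67, itm2cb fell by 3.26 ± 0.67, lratd1 fell by 2.44 ± 0.43, setmar fell by 2.36 ± 0.36 and the LIM-domain protein gene ajuba fell by 2.07 ± 0.39. The level of cpeb4a after LPS was similarly low, at -4.32 ± 1.11 (SD, n = 4). Adjusted p-values of these genes lay between 0.00108 for adam10b and 0.0435 for diabloa.

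Of 22 measured cytokine and chemokine genes, 9 rose in normally fed fish and none fell, and 15 were higher when p-values were adjusted over the list alone. The chemokine ccl34a.4 rose by 4.61 ± 0.81 (SE), the cytokine il34 by 3.31 ± 0.54 and the tumour necrosis factor gene tnfa by 3.97 ± 0.70. The median log2 difference of the list was 2.21, or 1.71 with genes below background set at their bound. Of 32 NF-kB and Toll-like receptor signalling genes, 5 rose, or 16 when adjusted over the list alone, with a median of 1.36. They included irak3, a negative regulator of Toll-like receptor signalling (4.08 ± 0.63, SE), the NF-kB inhibitor nfkbiaa (3.76 ± 0.60), the NF-kB subunit relb (2.83 ± 0.45) and the adaptor traf3 (2.71 ± 0.54). Of 23 genes of JAK-STAT and cytokine receptor feedback, 6 rose, or 12 when adjusted over the list alone, with a median of 1.19. Among them the receptor gene il4r.1 rose by 4.40 ± 0.85, the feedback inhibitor socs3b by 3.03 ± 0.53 and the AP-1 subunit junba by 3.01 ± 0.61. Of 30 immediate early genes, 5 rose, or 13 when adjusted over the list alone, with a median of 1.13, including ier2a (3.29 ± 0.54) and the growth arrest gene gadd45aa (2.95 ± 0.62). Of these genes nfkbiaa and traf3 were measured on 3 of the 4 PBS arrays and socs3b on 3 of the 4 LPS arrays.

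Against the other features of the array these lists stood higher in the camera test with a preset correlation, with an adjusted p of 2.42e-11 for cytokines, 1.35e-09 for NF-kB signalling, 2.44e-07 for JAK-STAT feedback and 2.66e-07 for immediate early genes. None of these calls held with an estimated correlation, where the adjusted p was 0.21 for cytokines and for NF-kB signalling with an estimated correlation and 0.51 for the other lists. In the self-contained fry test, which asks whether a list's genes move on balance in a single direction, the adjusted p was 0.00103 for cytokines and for NF-kB signalling, 0.0133 for JAK-STAT feedback and 0.0155 for immediate early genes. Within slide 3, with 1 LPS array, the list medians were 1.39 for cytokines, 1.37 for NF-kB signalling, 1.17 for JAK-STAT feedback and 1.15 for immediate early genes.

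Of 32 interferon-stimulated and antiviral genes, 4 rose in normally fed fish, or 15 when adjusted over the list alone, where 1 more was lower. The interferon regulatory factors irf1b and irf8 rose by 4.01 ± 0.61 and 3.95 ± 0.52 (SE), the suppressor socs1a rose by 2.59 ± 0.50, and socs1b rose at least 6.66-fold. The camera adjusted p of this list was 2.44e-07 with the preset correlation, and the adjusted p = 0.80 with an estimated correlation. Its median was 1.79 in the pooled comparison and 0.74 within slide 3. Of 37 apoptosis and p53 genes, 3 rose and 1, diabloa, fell, and 12 were higher and 1 lower when adjusted over the list alone. The initiator caspase casp9 rose by 2.87 ± 0.54 and the caspase-8 regulator cflara by 1.89 ± 0.36. The camera adjusted p was 1.19e-05 for this list, and the adjusted p = 0.51 with an estimated correlation. Of 24 macrophage markers, 2 rose, or 3 when adjusted over the list alone: acod1, which makes the antimicrobial metabolite itaconate, at least 7.55-fold, and the pore-forming protein gene mpeg1.2 by 4.56 ± 0.76. Their list had a camera adjusted p = 0.00788, and an adjusted p = 0.85 with an estimated correlation. Its median was 0.83 in the pooled comparison and 0.05 within slide 3. Markers of other cell types stood alike: the pooled and within-slide medians were 0.98 and 0.11 for endothelial markers, 0.88 and 0.06 for stellate cell and matrix genes, 0.93 and -0.41 for erythrocyte markers and 0.71 and -0.08 for pan-leukocyte markers, and no member of these lists passed.

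Among 19 acute phase protein genes, steap4, a metalloreductase, rose by 4.02 ± 0.82 (SE), and 5 were higher when adjusted over the list alone. The camera adjusted p of the list was 0.113, with a median of 0.18 in the pooled comparison and 1.16 within slide 3. LPS replicate 2 stood apart, with a list mean of -2.85 against 0.27 to 1.46 on the other 3 LPS arrays, and a level of hamp of 2.23 against 6.93 to 7.99. The serum amyloid gene saa differed by 4.41 ± 1.33 and the iron-regulatory hormone gene hamp by 3.36 ± 1.04, and neither passed over all features (adjusted p = 0.145 and 0.147). No cell cycle or oocyte gene passed. The 70 cell cycle genes had a median of -1.62 and a camera adjusted p of 2.21e-12, and the 18 oocyte and gonad genes a median of -2.73 and a camera adjusted p of 1.63e-05. Both had an adjusted p = 0.85 with an estimated correlation, and within slide 3 their medians were -1.54 and -1.79. The cell cycle list moved in the direction of the oocyte means of the pools given above, which are the measurement of the oocyte list itself.

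With slide as a fixed block, where the comparison rested on slide 3 with 1 LPS and 3 PBS arrays, 7 features passed, and with slide as a random block 82 passed. Within slide 3 the median of the features that rose was 2.94 against 3.26 in the pooled comparison, where features without overlap between the groups keep their sign by construction. The count fell to 68 without LPS replicate 1 of the normally fed fish, 53 without LPS replicate 3, 41 without LPS replicate 4, 48 without PBS replicate 1, 49 without PBS replicate 3 and 68 without PBS replicate 4, and was 203 without PBS replicate 2. It was 6 without the 4 arrays of highest oocyte mean, an alternative chosen after the data were seen.

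**Figure D2:**
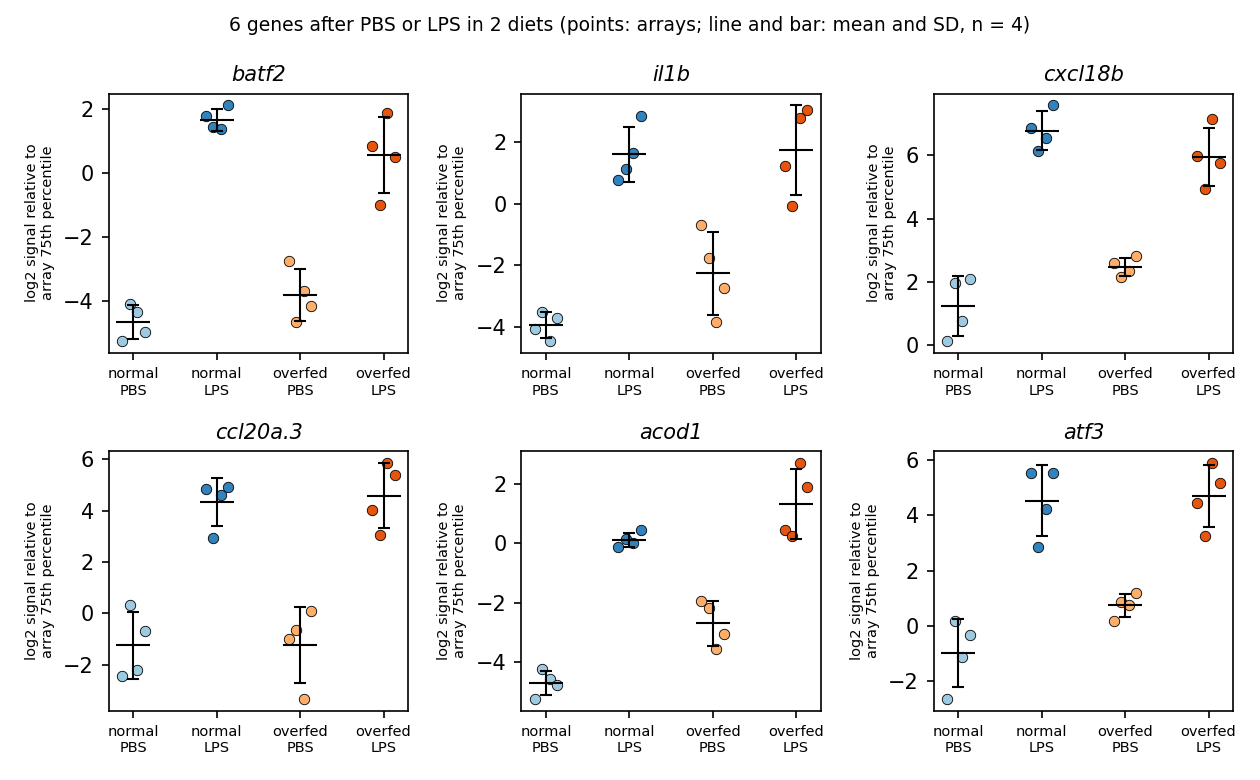
Log2 level relative to the array's 75th percentile of batf2, il1b, cxcl18b, ccl20a.3, acod1 and atf3 on each array, by diet and injection. Points are arrays, and bars give the group mean with the SD over 4 arrays. In both diets the 4 LPS arrays lie above the 4 PBS arrays for each gene, and the means of acod1 (-4.72), batf2 (-4.65) and il1b (-3.93) in normally fed fish given PBS were not well above background.

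In overfed fish single cytokine, chemokine and transcription factor genes rose after the same injection. The chemokine ccl20a.3 rose by 5.80 ± 0.83 on the log2 scale (SE, n = 4 arrays per group), from -1.22 ± 1.48 after PBS to 4.58 ± 1.27 after LPS (SD, n = 4). The cytokine il1b rose by 3.99 ± 0.73 (SE), from -2.25 ± 1.34 to 1.74 ± 1.46 (SD, n = 4), and the chemokine cxcl18b by 3.47 ± 0.51. The transcription factors batf2, atf3 and fosab rose by 4.36 ± 0.54, 3.94 ± 0.71 and 3.89 ± 0.58. The level of batf2 after PBS was low, at -3.8 ± 0.81 (SD, n = 4). In limma's test 21 features passed, 20 higher and 1 lower and all 21 without overlap between the groups, and 1028 had an unadjusted p below 0.05.

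The remaining named genes that rose in overfed fish were acod1, by 4.03 ± 0.52 (SE), irak3, by 3.73 ± 0.63, adam10b, by 3.59 ± 0.58, and ier2a, by 3.16 ± 0.54. The homeobox gene dlx3b was lower, at least 6.11-fold, from -0.05 ± 0.59 after PBS to -3.65 ± 1.03 after LPS (SD, n = 4), the latter not well above background. Adjusted p-values of the named genes ran from 0.00854 for batf2 and acod1 to 0.0482 for il1b.

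Of the 22 cytokine and chemokine genes, 3 rose in overfed fish, or 11 when adjusted over the list alone, with a median of 1.48, or 1.73 with genes below background set at their bound. Of the 32 NF-kB and Toll-like receptor signalling genes, irak3 and nfkb2 (2.17 ± 0.39, SE) rose, or 11 when adjusted over the list alone, with a median of 0.78. Of the 30 immediate early genes, atf3, fosab and ier2a rose, or 11 when adjusted over the list alone, with a median of 0.96. Camera gave an adjusted p of 4.30e-14, 1.83e-13 and 1.54e-16 for these lists, and an adjusted p = 0.094 for each with an estimated correlation. Of the 23 JAK-STAT feedback genes, socs3b rose by 2.99 ± 0.49, and 6 were higher when adjusted over the list alone. The camera adjusted p of this list was 1.85e-12, and the adjusted p = 0.14 with an estimated correlation. Of 24 macrophage markers acod1 rose, and 5 were higher when adjusted over the list alone, with a camera adjusted p of 5.40e-07 and an adjusted p = 0.31 with an estimated correlation. For all of these lists the fry test for a single direction did not pass, with an adjusted p of 0.0811 for cytokines. The list medians within slide 5 and within slide 1 were 1.18 and 0.71 for cytokines, 0.69 and 0.32 for NF-kB signalling, 1.18 and 1.14 for immediate early genes, 0.42 and 1.27 for JAK-STAT feedback and -0.04 and 0.71 for macrophage markers. In the same slides the oocyte and gonad list stood at 4.43 and 3.19 against 0.57 in the pooled comparison, the cell cycle at 1.58 and 0.75 against 0.07, and acute phase proteins at -0.89 and 2.62 against 0.08, so that the LPS and PBS arrays of a slide also differed in oocyte transcripts.

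No neutrophil, acute phase, pancreas or intestine gene passed over all features in overfed fish. The 20 neutrophil markers had a median of 0.94 (camera adjusted p = 6.56e-06, and adjusted p = 0.77 with an estimated correlation), with lyz, the lysozyme gene, at 2.73 ± 0.86 (SE), and a median of -0.27 within slide 5 and 0.67 within slide 1. The 22 genes of exocrine and endocrine pancreas had a median of -1.0 (camera adjusted p = 2.88e-05, and adjusted p = 0.98 with an estimated correlation), with the insulin gene ins at -5.81 ± 1.56 and the somatostatin gene sst2 at -5.23 ± 1.39. The 45 genes of fatty acid oxidation and ketone metabolism had a median of -0.57 and the 85 genes of oxidative phosphorylation a median of -0.40 (camera adjusted p = 1.61e-06 and 4.09e-07, and adjusted p = 0.92 and 0.98 with an estimated correlation).

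With slide as a fixed block no feature passed in limma's test, with 1667 at an unadjusted p below 0.05, and 7 passed with slide as a random block. The median of the features that rose was 3.18 within slide 5, with 1 LPS and 3 PBS arrays, and 3.88 within slide 1, with 1 array of each, against 3.75 in the pooled comparison, and their sign was fixed by the lack of overlap. No feature passed after normexp background correction, with the arrays of these 2 groups alone or without the arrays of slide 1 (939, 794 and 550 at an unadjusted p below 0.05 in limma), and 1 passed without the 4 arrays of highest oocyte mean, the last 2 of these alternatives being chosen after the data were seen. The count of 21 fell to 7, 3 and 0 without LPS replicates 1, 3 and 4 of the overfed fish and to 2, 12, 4 and 8 without their PBS replicates 1, 2, 3 and 4. It was 34 without LPS replicate 2 of the overfed fish. Because all arrays shared an estimate of the spread, it also fell to 11, 5 and 9 without PBS replicates 2, 3 and 4 and to 7 and 12 without LPS replicates 3 and 4 of the normally fed fish.

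The LPS effects in the 2 diets were compared across the 15021 features. The differences share no arrays, but the calls take their spread from all 16. Of the features called higher in normally fed fish (121) and in overfed fish (20), 18 were called in both, and none of those called lower was shared. The 18 included acod1, adam10b, atf3, batf2, ccl20a.3, cxcl18b, ier2a, il1b, irak3, nfkb2 and socs3b. Of the 131 features called in normally fed fish, 127 had the same sign in overfed fish, with a median log2 difference of 3.18 in normally fed and 1.57 in overfed fish, and all 21 features called in overfed fish had the same sign in normally fed fish. Independent lists would share 0.161 features, which is not the value without an effect here because of the shared spread. With the arrays of each diet fitted alone, 161 features passed in normally fed fish, of which 146 had the same sign in overfed fish, and none passed in overfed fish in limma's test, with 794 at an unadjusted p below 0.05. Features were chosen for their size in the diet named first, which inflates the median in that diet. Across all features, which are not independent replicates, Pearson's r of the effects was 0.15 and Spearman's rho was 0.077. Pearson's r was -0.10 with slide as a fixed block and -0.03 with slide as a random block, and -0.19 without PBS replicate 3, -0.10 without LPS replicate 3 and 0.41 without LPS replicate 1 of the overfed fish.

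Whether overfeeding altered the response to LPS was tested as the difference of the LPS effects. For the chemokine cxcl18b the difference of the effects, overfed minus normally fed, was -2.07 ± 0.73 on the log2 scale (SE, 4 arrays in each of 4 groups), for the interferon gene ifnphi1 the difference was -2.18 ± 0.59, and for atf3 it was -1.56 ± 1.01, none of which passed (adjusted p = 0.532, 0.532 and 0.547). For ccl20a.3 the difference was 0.22 ± 1.17, for irak3 -0.35 ± 0.88 and for socs3b -0.04 ± 0.72. No feature passed in limma's test of the difference. The lowest adjusted p was 0.532, 1318 features had an unadjusted p below 0.05, and the authors' deposited table, tested the same way, also gave 0. The genes that passed the threshold in normally fed fish alone were therefore not shown to respond differently in overfed fish.

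By gene list, 16 of 41 lists passed camera with the preset correlation for the difference of LPS effects, none passed with an estimated correlation (adjusted p = 0.96 with an estimated correlation for each of the 16), and none passed the fry test. Of the 16 calls, 8 held without PBS replicate 1 of the normally fed fish and 16 held without their PBS replicate 4. These were the lowest and highest numbers over the arrays left out. With the oocyte list mean as a covariate, chosen after the data were seen, 5 held. The oocyte list is among the 16, and its mean difference was removed by construction, because its own mean was the covariate. The 32 interferon-stimulated genes had a median difference of -1.85 (camera adjusted p = 6.95e-05), with the RNA sensor gene dhx58 at -2.70 ± 1.57 and ifit8 at -2.62 ± 1.95 (SE). The 22 cytokine genes had a median of -1.08 (camera adjusted p = 0.0415). The 18 oocyte and gonad genes had a median of 3.27 (camera adjusted p = 1.85e-07), with piwil1 at 4.68 ± 1.93 and nanos3 at 4.66 ± 1.90, and the 70 cell cycle genes a median of 1.79 (camera adjusted p = 4.16e-14). The cell cycle list moved in the direction of the oocyte means of the pools, the measurement of the oocyte list itself, which stood at 2.39 after PBS and -0.27 after LPS in normally fed fish.

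To ask how the diets differ in fish not given LPS, overfed and normally fed fish were compared 3 hours after injection of PBS. Single genes of the ribosome, mitochondria, clock and sterol regulation were among those higher in overfed fish. The ribosomal protein genes rpl24 and rps2 were higher in overfed fish by 2.52 ± 0.51 and 2.48 ± 0.54 on the log2 scale (SE), from 4 arrays per group except that rpl24 was measured on 3 of the 4 arrays of overfed fish. The cytochrome c oxidase genes cox5b2 and cox5bb were higher by 2.85 ± 0.62 and 2.47 ± 0.54, the clock gene per1a by 2.88 ± 0.65, and insig1, which restrains sterol synthesis, by 2.64 ± 0.49. In limma's test 430 features passed, 402 higher and 28 lower in overfed fish, and 3742 had an unadjusted p below 0.05. Of the 430, 423 had no overlap between the groups, and the split was 1920 higher and 470 lower after normexp background correction. With the brightness of the array as a covariate, an alternative chosen after the data were seen, 0 passed in limma's test, with 849 at an unadjusted p below 0.05, so these differences were not separated from the lower signal of the arrays of overfed fish. Brightness lay mostly lower in overfed fish and is log2 of the percentile subtracted from every level. Values with this covariate therefore cannot separate diet from brightness.

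The named genes with the largest rises in overfed fish given PBS were rnf11b, a RING finger protein gene, by 5.2 ± 1.33 (SE), mvb12bb, a subunit of the endosomal sorting complex, by 5.19 ± 1.33, and tac4, a tachykinin gene, from -1.36 ± 0.66 to 3.54 ± 0.95 (SD, n = 4). The deubiquitinase gene usp8 rose by 4.55 ± 1.14, the plasminogen receptor gene plgrkt by 4.47 ± 1.1, the transcription factor gene rfx1a by 3.89 ± 0.83 and the mitochondrial cyclophilin gene ppifb, measured on 3 of the 4 arrays of normally fed fish, by 3.84 ± 0.84. The cerebellin gene cbln6 rose at least 9.52-fold, the urotensin gene uts2b at least 6.78-fold and trim59 at least 3.56-fold, from levels not well above background in normally fed fish. Adjusted p-values of these genes lay between 0.0251 and 0.05.

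Of the 28 features lower in overfed fish given PBS, hprt1l, related to the purine salvage enzyme, fell by 3.01 ± 0.54 (SE). The mitochondrial exonuclease gene mgme1 fell at least 2.47-fold and echdc1, which encodes a decarboxylase that removes ethylmalonyl-CoA, fell at least 3.09-fold, both to levels not well above background. The replication fork gene timeless fell by 1.91 ± 0.38, the nuclear import receptor gene tnpo2a by 2.0 ± 0.45, mettl6, a tRNA methyltransferase gene, fell by 2.0 ± 0.46 and elac1, a tRNA 3' processing gene, fell by 1.84 ± 0.46. The glycosyltransferase gene pomgnt1 fell by 1.91 ± 0.49 and the deubiquitinase gene atxn3 fell by 1.71 ± 0.43. The prolyl hydroxylase gene p4htma differed by -1.72 ± 0.41 (adjusted p = 0.0423), but its difference was 0.22 after normexp background correction and 0.59 with no filter on dim probes.

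Of 85 measured genes in the cytosolic ribosomal protein list, 22 were higher in overfed fish given PBS and none lower, and 78 were higher when adjusted over the list alone. The median log2 difference was 1.72, with rpsa, measured on 3 of the 4 arrays of overfed fish, at 2.47 ± 0.53 (SE), and the camera adjusted p was 4.76e-26, with an adjusted p = 0.91 with an estimated correlation. With the brightness of the array as a covariate the median turned to -0.2 and did not pass (adjusted p = 0.587). The list also holds kinases that phosphorylate ribosomal protein S6, of which rps6kb1a was higher at least 2.26-fold. The list mean was lower on brighter arrays, with Pearson's r of -0.98 against log2 of the 75th percentile over the 8 arrays of normally fed fish and -0.93 over the 8 arrays of overfed fish (exact permutation p = 0.00055 and 0.00094, two-sided, adjusted p = 0.00066 and 0.00094 over 6 relations). Spearman's rho was -0.93 and -0.95 (exact permutation p = 0.0022 and 0.0011), and r was -0.90 and -0.92 without the 2 arrays farthest from the median brightness. Part of this relation is built in, since every level has the 75th percentile of its array subtracted. In a test chosen after the data were seen, the list mean minus the mean of all tested features on the same array, in which that percentile cancels, had a Pearson's r of -0.97 and -0.93 (exact permutation p = 5e-04 and 9.9e-05, adjusted p = 0.00066 and 2e-04), a Spearman's rho of -0.93 and -0.98 (exact permutation p = 0.0022 and 4e-04), and an r of -0.90 in both diets without the 2 farthest arrays.

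**Figure D3:**
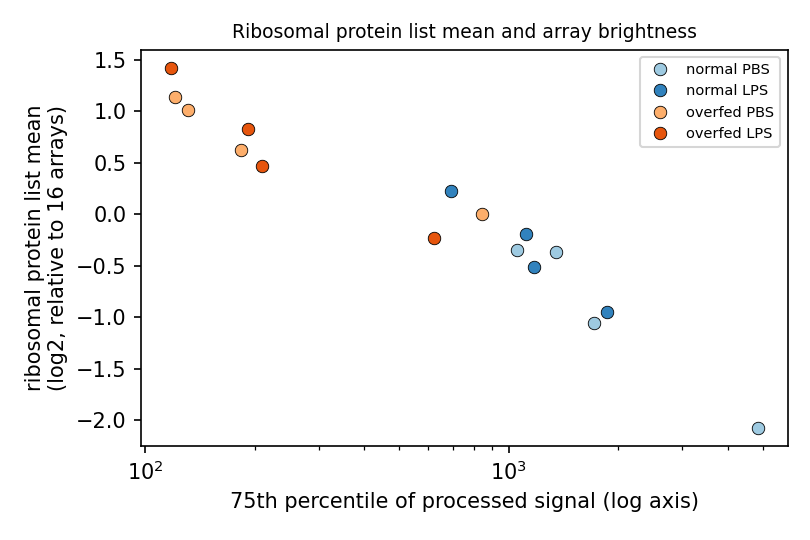
Mean log2 level of the 85 measured genes of the cytosolic ribosomal protein list on each array, relative to each gene's mean over all arrays, against the array's 75th percentile of processed signal on a log axis. Points are the 16 arrays by diet and injection. The list mean is lower on brighter arrays, from 1.42 to -2.07, with r = -0.98 within normally fed and r = -0.93 within overfed fish, part of which is built in because each level has the percentile on the x axis subtracted.

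Of 85 oxidative phosphorylation genes, 6 were higher in overfed fish given PBS, or 27 when adjusted over the list alone, with a median of 0.77. They included cox7a1 (1.82 ± 0.45, SE) and cox7c (1.49 ± 0.37), and the camera adjusted p was 1.42e-10, with an adjusted p = 0.91 with an estimated correlation. Of 35 circadian clock and output genes, 4 rose, namely per1a, dbpa (2.32 ± 0.57), per3 (2.07 ± 0.41) and per2 (1.49 ± 0.30), and 7 were higher and 1 lower when adjusted over the list alone. Of 34 genes of cholesterol synthesis and uptake, 3 rose, or 4 when adjusted over the list alone. They were insig1, insig2 (1.82 ± 0.45) and soat1, which esterifies cholesterol (2.1 ± 0.53). Of 54 unfolded protein response genes, 3 rose, the same number as when adjusted over the list alone: the stress sensors ern1 (2.91 ± 0.65) and atf6 (1.59 ± 0.37) and the disulphide isomerase gene pdia3 (1.80 ± 0.36). Of these genes cox7c and insig2 were measured on 3 of the 4 arrays of overfed fish. Camera did not pass for the clock, cholesterol or unfolded protein lists (adjusted p = 0.0644, 0.101 and 0.101).

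Further metabolic and immune genes that rose in overfed fish given PBS were pfklb, a phosphofructokinase subunit gene (2.70 ± 0.50, SE, measured on 3 of the 4 arrays of normally fed fish), ass1, which encodes the urea cycle enzyme argininosuccinate synthase (2.23 ± 0.41), and agpat2, an enzyme gene of glycerolipid synthesis (1.83 ± 0.42). The interferon regulatory factor irf3 rose at least 2.31-fold, the phospholipase gene pla2g1b of the exocrine pancreas at least 2.45-fold and acod1 at least 1.07-fold. The coagulation inhibitor gene tfpia rose by 2.37 ± 0.52, the collagen gene col1a1b by 2.35 ± 0.58 and the chaperone gene hsp90ab1 by 1.97 ± 0.46. No oocyte or cell cycle gene passed, and their medians were -4.22 and -1.49 (camera adjusted p = 3.06e-07 and 1.42e-10, and adjusted p = 0.91 for both with an estimated correlation).

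With slide as a random block 68 features passed after PBS, and with the oocyte list mean as a covariate, also chosen after the data were seen, 1 passed. With the PBS arrays alone 1 passed, and without the 4 arrays of highest oocyte mean 0 passed in limma's test, with 1986 at an unadjusted p below 0.05. The count fell from 430 to 22 and 21 without PBS replicates 1 and 3 of the normally fed fish, to 25 and 24 without PBS replicates 2 and 4 of the overfed fish, and to 280, 215 and 245 without LPS replicates 1, 3 and 4 of the normally fed fish, and it was 1064 without PBS replicate 2 of the normally fed fish, 974 without PBS replicate 3 and 715 without LPS replicate 4 of the overfed fish.

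The same comparison of diets after LPS gave lower levels of a pair of lipid-handling genes in overfed fish. The gene dgat1a, which encodes an enzyme of the last step of triglyceride synthesis, fell by 3.34 ± 0.52 on the log2 scale (SE), from 3.43 ± 0.42 in normally fed to 0.09 ± 0.49 in overfed fish (SD, n = 4). The fatty acid binding protein gene fabp1b.2 fell by 3.29 ± 0.58 and mylipb, related to a ubiquitin ligase of the LDL receptor, fell at least 2.89-fold. The receptor gene tnfrsf9b of the tumour necrosis factor receptor family was higher by 2.64 ± 0.41. In limma's test 19 features passed, 10 higher and 9 lower in overfed fish, and 2813 had an unadjusted p below 0.05. All 19 were without overlap between the groups, and the split was 2298 higher and 1596 lower after normexp background correction, 9 and 13 after quantile normalization, 89 and 27 after centring on the median of detected probes and 47 and 17 in the authors' deposited table. In limma's test 0 passed with no filter on dim probes and 0 with a trended and robust prior, with 3255 and 2852 at an unadjusted p below 0.05.

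Also higher in overfed fish after LPS were unc5cb, a netrin receptor gene (2.54 ± 0.39, SE), map7d3, a microtubule-binding protein gene (2.43 ± 0.41), plekhm2 (2.24 ± 0.40), gng7, a G-protein gamma subunit gene (2.19 ± 0.39), and mctp2b (2.14 ± 0.38). The deubiquitinase gene mindy2 was higher at least 1.77-fold and the axonemal dynein gene dnai1.2 at least 1.61-fold. Lower were mxd, an Mx GTPase gene (fell by 3.28 ± 0.57), the transcriptional co-regulator gene cited2 (fell by 3.13 ± 0.50), the galanin receptor gene galr1b (at least 3.28-fold) and dlx3b (at least 5.17-fold). The level of mxd in overfed fish, -4.13 ± 0.72 (SD, n = 4), was below that of dlx3b, -3.65 ± 1.03, which has only a bound. Adjusted p-values of the named genes lay between 0.0414 and 0.0486.

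Of 33 genes of fatty acid and triglyceride synthesis, dgat1a was the member that passed, also when adjusted over the list alone, and the list had a camera adjusted p = 0.865. No member of the other lists passed over all features. The medians of the hepatocyte secretory lists were higher in overfed fish, at 1.58 for 33 complement genes, 1.46 for 24 coagulation genes and 1.38 for 34 hepatocyte identity genes (camera adjusted p = 0.00035, 8.23e-06 and 0.000244, and adjusted p = 0.96 for each with an estimated correlation). Complement c3a.2, measured on 3 of the 4 arrays of overfed fish, differed by 2.95 ± 1.03 (SE), the coagulation factor gene f7i by 2.3 ± 0.93 and the liver fatty acid binding protein gene fabp10a by 2.66 ± 0.85. These lists moved with LPS replicate 2 of the normally fed fish, whose hepatocyte list mean of -3.14 lay below those of the other 3 arrays of its group, 0.00 to 0.52. The 85 genes of the cytosolic ribosomal protein list had a median of 1.05 (camera adjusted p = 1.06e-19, and adjusted p = 0.96 with an estimated correlation), and no member passed. With the brightness of the array as a covariate the median turned to -0.42 and the list passed camera in the lower direction (adjusted p = 0.0436). This is no evidence of lower levels in overfed fish, since brightness nearly separates the diets and is the percentile subtracted from every level. The 21 intestinal epithelium genes had a median of -1.89 (camera adjusted p = 0.000264, and adjusted p = 0.96 with an estimated correlation), with the peptide transporter gene slc15a1b at -2.66 ± 0.74. The growth factor gene igf1 stood at 4.41 ± 1.01 and did not pass (adjusted p = 0.0834).

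With slide as a random block no feature passed after LPS, with 1774 at an unadjusted p below 0.05, and the brightness covariate also left 0, with 2315. The count of 19 depended on each array: leaving out PBS replicate 2, 3 or 4, or LPS replicate 1, 2 or 3, of the normally fed fish gave 0, as did leaving out PBS replicate 2 or 4 or LPS replicate 2 or 3 of the overfed fish. It was 2 without LPS replicate 4 and 41 without PBS replicate 1 of the normally fed fish, and 8 and 72 without LPS replicates 1 and 4 and 33 and 66 without PBS replicates 1 and 3 of the overfed fish. The diet effects after PBS and after LPS, which share no arrays, had a Pearson's r of 0.412 across features. Both comparisons share slides and scan days, each of a single diet, so this r does not separate diet from slide, scan day or array brightness.

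The share of features whose measured arrays of a group did not overlap those of the other was 15.68% for LPS in normally fed fish, 3.36% for LPS in overfed fish, 13.94% for diet after PBS and 13.89% for diet after LPS, against 2.86% by chance for 4 arrays against 4. The median log2 difference over all features was 0.23, -0.15, 0.16 and -0.13 in the same order and -0.36 for the difference of LPS effects. After quantile normalization these medians were 0.12, -0.07, -0.02, -0.15 and -0.17, and after centring on the median of detected probes 0.07, -0.10, 0.06, -0.02 and -0.15, and no gene list called with the planned values changed its direction under either scaling.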

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

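The tests of ovarian RNA with features ranked on the PBS arrays alone, of features called on the normally fed arrays alone, of slide and scan day, of an array-wide loss of signal, of the LPS injection as a source of a low hepatocyte mean and of array brightness were chosen after the result was seen, and so were the alternatives with oocyte, hepatocyte or brightness covariates. The list of kidney genes was written after the leading genes of the array in question had been seen, and those genes, cubn, amn and slc22a6l, were left out of it.

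After PBS most called features were higher in overfed fish, 402 of 430. The tables do not exclude ovarian RNA as a contributor: over the 8 LPS arrays, which enter this comparison through the shared spread, the median slope of the 402 features on the oocyte list mean within groups was -0.147, below the 2.5th percentile of 1000 matched sets (-0.10, median -0.08), 87.3% of them had a slope below 0 against 68.7% of all features, and the 402 features of highest t on the PBS arrays alone, 276 of them among the called ones, had a median slope of -0.17 (2.5th percentile of matched sets -0.088). With a difference of -3.75 in the oocyte mean, overfed minus normally fed, the slopes of the called features imply a median log2 difference of 0.55 against 2.36 observed. The 2.36 is inflated because these features were chosen for passing in this comparison. Ovarian RNA may account for part of the difference, and the size of that part is not settled. With the oocyte mean as a covariate 0 of the 20 named genes passed and all 20 kept their sign. Without the 4 arrays of highest oocyte mean 0 of the 20 also passed. There their sign was fixed by the lack of overlap between the groups and tells nothing. Slide and scan day cannot be told apart from diet, since each slide and day holds a single diet, and 68 features passed with slide as a random block. Diet itself stays open, and chance cannot be excluded, because 2 of 35 splits of these arrays gave as many features and the highest other split, with normally fed PBS replicates 1, 3 and 4 and overfed PBS replicate 3 on a side, called 2173, which points to a structure of the samples that follows their oocyte means.

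Normally fed LPS replicate 2 stood low in hepatocyte transcripts, with a list mean of -3.14. The tables argue against an array-wide loss of signal, since 55.7% of its spots were well above background (35.7% to 77.6% on the others) and its 75th percentile of signal, 1865, was above all but 1 of the others, while its spike-in slope of 1.079, just above the highest other (1.077), was not counted against a loss, because treating only a low value as a loss was fixed after the slope was seen. They also argue against the LPS injection alone, since the lowest of the other 3 LPS arrays of that group stood at 0 and the lowest PBS array at -1.62. Kidney tissue in the pool may be a candidate source and stays open: the mean of 23 measured of 48 kidney genes was 0.48 on this array (highest other 0.65, median other 0.13), with 12 genes at least 1 above their mean, the level of slc6a19b, the highest of the list, at 6.34 (median of the others 4.77), that of miox at -5.65 (median of the others -0.65), and 2 of the list in other lists, but the 2 arrays with higher kidney means, overfed PBS replicate 2 (0.65) and normally fed LPS replicate 4 (0.61), had hepatocyte means of 0.98 and 0.52, and levels of cubn and amn of 6.52 and 4.07 and of 5.12 and 3.79 against 5.83 and 3.98 on this array. No biological explanation besides the injection was tested.

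The cytosolic ribosomal protein list had a median of 1.72 in overfed against normally fed fish after PBS, where 22 of 85 genes passed, and of 1.05 after LPS, where none passed, with an adjusted p = 0.91 and 0.96 with an estimated correlation, and with brightness as a covariate the medians were -0.2 and -0.42 (adjusted p = 0.587 and 0.0436). The medians with brightness decide nothing about diet, since brightness nearly separates the diets and is the percentile subtracted from every level. The tables argue against ovarian RNA as the whole cause, since the median after PBS was 1.35 with the oocyte mean as a covariate against 1.72 without. Brightness of the array may contribute: the list mean minus the mean of all features on the same array, in which the subtracted 75th percentile cancels, was lower on brighter arrays within each diet, with r nearest to 0 at -0.93, and the overfed arrays of slide 1, which were brighter, lay with the normally fed arrays. Compression of strong signals cannot be told apart, since the list stood at percentile 98.1 of 10000 lists of matched level after PBS (median 1.53, 95th percentile 1.68) but at percentile 46.9 after LPS (1.08 and 1.19, against 1.05). The match was incomplete, with a median mean level of 8.01 for the matched features against 8.24 for the list. The percentiles may therefore stand too high if the difference grows with signal. Diet stays open and is confounded with scan day.

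With arrays taken as exchangeable, the splits argue against chance for LPS in normally fed fish. Here 1 of 35 splits, the real one with 131 features, gave as many, and the highest other gave 0. This is the lowest share that the test can give. Slide 4 held only LPS arrays of these fish, so the arrays were not fully exchangeable, and 82 features passed with slide as a random block. For diet after LPS 1 of 35 splits, the real one with 19 features, gave as many, and the highest other gave 1. Among exchangeable arrays this argues against chance, again at the lowest share the test can give. However, 0 of the 15 named genes passed with no filter on dim probes, with a trended and robust prior, or with any of several single arrays left out. Slide and scan day are not excluded, since each slide holds a single diet. With slide as a random block 0 features passed in limma, with 1774 at an unadjusted p below 0.05, and 0 of the 15 named genes. For LPS in overfed fish the splits alone do not exclude chance, with 3 of 35 giving 21 or more, and 7 features passed with slide as a random block. The highest other split, with overfed PBS replicates 1 and 3 and LPS replicates 1 and 4 on a side, called 328, which points to a structure of the samples: the oocyte means of those 4 arrays, -1.52, 2.91, 2.78 and 1.23, lay above those of the other 4, -4.55, -2.28, -3.03 and -4.01. Of the 20 features called higher 18 were also called higher in normally fed fish, but both calls use the spread of all 16 arrays. For the 161 features called on the normally fed arrays alone, 1 of 35 splits of the overfed arrays, the real one, gave as large a median. This median was 1.45, in the direction of the normally fed fish. The highest other split, which exchanges PBS replicate 4 and LPS replicate 1, also rounds to 1.45, so the rank does not exclude chance. For the difference of LPS effects between diets the real count of 0 fixes the outcome, so that 100 of 100 drawn splits, the highest with 5, decide nothing.

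An array was singled out where its gap to the nearest of the 4 arrays of its group, divided by the range of the group, was above Dixon's 95% critical value, which chance gives in about 1 in 20 groups, and 18 of 300 groups met it. This share was 0.921 for the spike-in slope of normally fed PBS replicate 1 (slope 1) and 0.833 for that of overfed PBS replicate 1 (0.87). In normally fed LPS replicate 2 it was 0.896 for the complement list mean (-2.87), 0.923 for coagulation (-3.62), 0.857 for hepatocyte identity and 0.956 for glucose and glycogen metabolism (-0.65). It was 0.871 for the cytokine list mean of normally fed LPS replicate 4 (1.47). In overfed fish given PBS it was 0.919 for lymphocyte markers (replicate 3, -1.43), 0.878 for oxidative stress and metal response (replicate 2, 0.46) and 0.87 for the cell cycle (replicate 3, 1.38). In overfed fish given LPS it was 0.833 for the share of spots well above background (replicate 2, 35.7%), 0.877 for hepatocyte identity (replicate 1, -0.26) and 0.831 for ribosome biogenesis (replicate 4, -0.72). Among named genes it was 0.916 for mxf in normally fed PBS replicate 1 (-4.82), 0.861 for tac4 in the same array (-2.34), 0.846 for ccl20a.3 in normally fed LPS replicate 2 (2.92), 0.846 for timeless in overfed PBS replicate 4 (-2.24) and 0.919 for mylipb in overfed LPS replicate 2 (-3.58).

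The difference of the LPS effects, overfed minus normally fed, passed camera with the preset correlation for 16 lists and for none with an estimated correlation (adjusted p = 0.96 for each). The median differences of immune and vascular lists were -1.08 for cytokines (adjusted p = 0.0415), -1.85 for interferon-stimulated genes (6.95e-05), -0.87 for apoptosis (0.0184) and -1.09 for endothelial markers (0.0322). Those of other tissues were -2.19 for pancreas (4.67e-05), -1.58 for intestine (0.0184), -1.01 for adipose and lipid droplet genes (0.0296) and 3.27 for oocyte and gonad transcripts (1.85e-07). Those of metabolism were -0.9 for fatty acid oxidation (6.95e-05), -0.94 for oxidative phosphorylation (4.16e-14), -0.76 for oxidative stress (0.0216) and -0.75 for xenobiotic metabolism (0.0184). The remaining ones were 1.79 for the cell cycle (4.16e-14), -0.69 for ribosomal proteins (0.00345), 0.03 for ribosome biogenesis (0.0351) and -0.46 for the proteasome (0.0256).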

How the results depend on the processing

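The tests with oocyte, hepatocyte or brightness covariates, with scan day as a block, and with the arrays of slide 1 or the 4 arrays of highest oocyte mean left out were chosen after the data were seen. Counts below are in the order LPS in normally fed fish, LPS in overfed fish, diet after PBS and diet after LPS, which were 131, 21, 430 and 19 as planned, and the cause was not tested unless given. Normexp background correction gave 759, 0, 2390 and 3894, with a fixed offset that was large against the signal of most overfed arrays and may act unequally on the diets. Quantile normalization gave 35 for LPS in overfed fish and 177 for diet after PBS, and centring on the median of detected probes gave 664 and 116 for diet after PBS and after LPS. No filter on dim probes gave 76, 12, 111 and 0, and probes well above background on all 16 arrays gave 57, 9, 200 and 2, with fewer features tested. Every probe as its own feature gave 677 and 47 for diet after PBS and after LPS. The arrays of the compared groups alone gave 0, 1 and 9 for LPS in overfed fish, diet after PBS and diet after LPS, with fewer arrays. Slide as a fixed block gave 7 and 0 for LPS, which rests on fewer arrays, and slide as a random block (consensus correlation 0.224) gave 82, 7, 68 and 0. Array weights gave 3200, 10, 3466 and 854, with a weight of 11.53 for normally fed PBS replicate 4. A trended and robust prior gave 276 and 0 for diet, a threshold of 0.01 gave 39, 2, 11 and 0, and the authors' deposited table gave 64 for diet after LPS. The oocyte covariate gave 50, 49, 1 and 535, both the oocyte and hepatocyte covariates gave 89 for LPS in overfed fish and 2 for diet after PBS, and brightness gave 85 for LPS in normally fed fish and 0 for both diet comparisons. Without the arrays of slide 1 the counts were 0, 657 and 115 for LPS in overfed fish and diet after PBS and after LPS, without the 4 arrays of highest oocyte mean 6, 1, 0 and 469, and with scan day as a fixed block 9 for LPS in overfed fish. Beside the counts of 0 in limma, features at an unadjusted p below 0.05 for LPS in overfed fish numbered 939 with normexp, 794 in the compared groups alone, 1667 with slide fixed and 550 without slide 1. For diet after PBS they numbered 849 with brightness and 1986 without the 4 arrays, and for diet after LPS 3255 with no filter, 1774 with slide random, 2852 with the trended prior, 2813 at the threshold of 0.01 and 2315 with brightness. The difference of LPS effects gave 0 in limma under each alternative run, with 598 to 3051 at an unadjusted p below 0.05.

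Leaving out an array in turn gave 41 to 203, 0 to 34, 21 to 1064 and 0 to 72 features, with 707 at an unadjusted p below 0.05 for LPS in overfed fish without overfed LPS replicate 4, where 0 passed. The correlation across features of the LPS effects, 0.15 as planned, was -0.19 to 0.41 when an array was left out, -0.1 with slide as a fixed block, -0.03 with slide as a random block, 0.38 with the oocyte covariate and 0.43 with the oocyte and hepatocyte covariates. The median of the oocyte list for LPS in overfed fish ranged from -0.78 to 2.05.

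Gene list directions turned, by the sign of the median or of the test, in these cases. With normexp, ribosome biogenesis stood at -0.15 for LPS in overfed fish and -0.19 for the difference of LPS effects, and the insulin, leptin and growth hormone axis at 0.21 for diet after LPS. With slide fixed, pan-leukocyte markers stood at -0.08 for LPS in normally fed fish, erythrocyte markers at -0.67 for LPS in overfed fish and ribosome biogenesis at -0.73 for the difference (adjusted p = 0.000622, lower, against 0.03 and 0.0351, higher, as planned). With the oocyte covariate the oocyte list stood at -0.01 for LPS in normally fed fish and the cell cycle at -0.09 for diet after PBS. With both covariates pan-leukocyte markers stood at -0.12 and the oocyte list at 0.03 for LPS in normally fed fish, and complement at -0.35, hepatocyte identity at -0.17 and the cell cycle at 0.04 for diet after PBS. The oocyte values, and that of hepatocyte identity with both covariates, lay near 0 by construction, because the list's own mean was a covariate. With brightness, complement stood at -0.5, hepatocyte identity at -0.66, pancreas at -0.98 and ribosomal proteins at -0.2 for diet after PBS, and ribosomal proteins at -0.42 for diet after LPS (adjusted p = 0.0436, lower). Without the 4 arrays of highest oocyte mean, xenobiotic metabolism stood at -0.14 for LPS in normally fed fish and -0.03 for the difference, and ribosomal proteins at 0.11 for the difference. The gene p4htma stood at 0.22 with normexp and 0.59 with no filter, and the cause was not tested. Of these turned values, -0.73 and -0.42 passed the threshold and the others did not. The values with brightness cannot separate diet from brightness, which lay mostly lower in overfed fish.

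With the replicate number as a block the counts were 94, 1, 294 and 6. The numbers did not pair the arrays: 7 of 24 pairs with the same number had a correlation of deviations over 0.1 (range -0.49 to 0.61, median 0.04, against -0.04 for different numbers), and 4 of 16 arrays had their best match in their own number. The block changed no list call.

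Counts within 1.5 times of the planned ones, with the same main direction, were given by spots with outlier flags kept (134, 14, 332 and 20) and the mean of the probes of a gene (150, 17, 397 and 18). A log2 fold change of at least 1 changed no count and could not, since every called feature exceeded it, the smallest with 1.131 for diet after PBS. Signal over background limits the low end: genes not well above background in a group have only a bound, and the share of spots well above background was 35.7% to 77.6%.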

Other observations

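The genes in this part were chosen after their values were seen, and no further tests were run on them. Egg yolk precursor genes, made by the liver of females under oestrogen, spanned a wide range between pools of the same group. The level of vtg2 ran from -1.42 to 11.9 over the 16 arrays, with a group mean of 7.8 ± 0.7 (SD, n = 4) in normally fed fish given PBS and 7.71 ± 6.22 (SD, n = 4) in overfed fish given PBS. The level of vtg5 ran from 0.05 to 11.61 and that of vtg7 from 2.56 to 11.71, while the oestrogen receptor gene esr1 ran from -1.7 to 3.59. The labels used here do not give the sex of the fish in a pool.

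Class I histocompatibility genes also differed between pools. The level of mhc1uba was 5.69 ± 1.75 (SD, n = 4) in normally fed fish given PBS and 6.91 ± 0.4 (SD, n = 4) in normally fed fish given LPS, but -0.04 ± 5.18 and -0.82 ± 2.71 (SD, n = 4) in overfed fish given PBS and LPS, and that of mhc1uea ran from -5.03 to 4.91. Genes of the exocrine pancreas stood high on each array, with prss1, a trypsin gene, between 6.76 and 11.66 and ela2l, an elastase gene, between 6.27 and 10.66. The insulin gene ins ran from -1.93 to 7.86 and the ileal bile acid binding protein gene fabp6 from -3.18 to 10.38. The egg coat gene zp2.5 ran from -3.82 to 7.64 and the oocyte gene zar1 from -4.53 to 5.88. The muscle actin gene actc1b ran from -5 to 4.57. The iron-regulatory hormone gene hamp had a level of 2.72 ± 1.46 after PBS and 6.09 ± 2.61 after LPS in normally fed fish, and 3.95 ± 0.57 and 6.74 ± 1.04 in overfed fish (SD, n = 4).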
